A study of Mus musculus with 6 samples.

How the data were processed

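RNA was profiled in 6 libraries of mouse primary osteoblasts, the bone-forming cells, cultured from the calvaria (skull caps) of 1 d old C57BL/6J pups whose Mark3 alleles are flanked by loxP sites. Per the labels' protocols, cells received adenovirus carrying either GFP (3 libraries, called WT) or the Cre recombinase (3 libraries, called Mark3-KO) for 24 h. RNA was taken up in Trizol and libraries were made with the TruSeq RNA kit version 2, a kit that does not mark strand, per the labels' protocols. Genotype and virus therefore changed together.

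The values were whole-number counts per gene, as deposited by the authors, in 1 table of 51912 Ensembl gene IDs and 6 columns named for the samples. Per the submitters' processing notes, FastQC, HISAT2 2.0.5, StringTie and DESeq2 were used with the genome build GRCm38. Their order, settings and annotation release, and how reads of overlapping genes or of several positions were counted, were not given in the sources used here. Counts summed to between 56925883 and 71445243 per library. Of the IDs, 51719 matched the GENCODE mouse release M21 annotation of GRCm38, which gave symbols and coordinates, and 193 did not. The unmatched IDs took 0.033 to 0.083% of a library's counts. They stayed in the table under their IDs, and 18804 genes had a total count of 0.

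No 2 libraries were copies of each other. Over genes with enough counts, the chi-square per degree of freedom between pairs of libraries ran from 58.7 to 641, and from 67.6 to 207 within a group. The lowest value, 58.7, was between WT replicate 3 and Mark3-KO replicate 1, a pair from opposite groups. The labels do not say whether libraries of a group came from separate cultures or litters, so p-values measure only the spread between these libraries, which may be technical.

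The comparison of Mark3-KO with WT was made with edgeR 4.0.16 under R 4.3.3. Genes were kept with filterByExpr (19017 tested), libraries were scaled with TMM, and edgeR's quasi-likelihood test was followed by Benjamini-Hochberg adjustment with a threshold of 0.05. Fold changes are log2 values of Mark3-KO over WT, and levels are CPM on TMM-scaled library sizes. Standard errors were taken as the log2 fold change over the square root of the F statistic. The test, the scaling, the gene lists, the rule for named genes and most alternatives were set before the data were examined.

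The rule for named genes took Mark3, its family members Mark1, Mark2 and Mark4, and Jag1 whatever their values. Among genes past the threshold with a mean of at least 1 CPM and no overlap between the groups, it took up to 10 with the largest fold change in each direction, leaving out predicted models and clones. In each list it took up to 4 members with the smallest p. It also took the shares of mitochondrial genes, ribosomal protein genes and the top 20 genes. Not every gene that the rule takes is reported here. Genes outside the rule are marked in the text as chosen after their values were seen. A fold against a group without counts used a floor of 3 counts over the group. Ratios with 1 to 3 counts in a group carry exact 95% binomial intervals. Intervals and floors cover counting error alone.

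There were 29 lists of genes. Those of pathways covered LKB1-dependent AMPK-related kinases, genes neighbouring Mark3, Notch ligands, receptors and processing, Notch target genes, osteoblast differentiation and mineralisation, osteoclast regulators made by osteoblasts, the Wnt pathway, the BMP and TGF-beta pathway, and YAP and TEAD target genes. They also covered extracellular matrix, the actin and microtubule cytoskeleton, p53 target genes, the type I interferon response, NF-kB and inflammatory mediators, the cell cycle, immediate early genes, cholesterol biosynthesis, the unfolded protein and ATF4 response, and hypoxia and glycolysis. Markers of other cells covered endothelial, macrophage and osteoclast, chondrocyte, skeletal muscle, adipocyte, pericyte and smooth muscle, Schwann, epithelial and red blood cells. A list of sex-linked genes was a technical check. The 26 pathway and cell lists with at least 3 tested members were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, adjusted over the lists. Camera compares a list with all other genes. It was repeated with an estimated correlation, and with fry, which tests whether a list moves one way on balance without comparing it with other genes.

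Alternatives were DESeq2 size factors, library size alone, the DESeq2 1.42.0 Wald test, limma-voom, no filter on low counts, a filter of 1 CPM in 3 libraries, the replicate number as a block, and leaving out each library in turn. Added after seeing the data were a GC correction, a fit of the 4 libraries nearest to each other on the first principal component, and an adjusted p threshold of 0.1. The GC correction entered a natural spline with 6 degrees of freedom, fitted per library to the log2 ratio of each gene to its mean over libraries against the GC content (the share of G and C bases) of the gene's longest transcript, as an offset in the same edgeR fit. A GC value existed for 18965 tested genes (99.7%). Because the groups themselves differed along GC content, this correction also removes any true change that follows GC content. Exon overlaps between genes were found with bedtools 2.31.1. For each gene the nearest tested genes on the same strand, with a gap of at most 50 kb, were also examined, a step added after seeing the data. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.

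The procedure was tested on simulated counts for the comparison of Mark3-KO with WT, with 200 genes drawn to be changed. Without a GC trend (18630 genes), it recovered 10.4% of genes changed by 1 on the log2 scale and 68.8% of those changed by 2, with 8 false calls. This simulation used the gene-wise dispersions of the uncorrected fit (common dispersion 0.0708). Those with the trend used dispersions of the GC-corrected fit (common dispersion 0.045), so recovery with and without the trend cannot be compared. With the GC trend of the libraries added and no correction (18694 genes), it recovered 51% and 92.9%, with 2233 false calls. With the trend and the GC correction (18643 genes), it recovered 42.4% and 87.9%, with 13 false calls. Camera gave an unadjusted p under 0.05 for 6 of 100 lists without a change and a p of 7.67e-22 for a shifted list (18704 genes). These counts were drawn for each gene separately, without a GC trend and at a fixed dispersion below the common dispersion of the libraries. The check therefore does not give camera's error rate in these data, where genes may move together.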

Results

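Gene counts were compared between primary calvarial osteoblasts of Mark3 flox/flox pups given Cre adenovirus (Mark3-KO, 3 libraries) and those given GFP adenovirus (WT, 3 libraries). The comparison asks which transcripts differ after 24 h of exposure to Cre or GFP adenovirus, where Cre deletes Mark3, a serine/threonine kinase that phosphorylates microtubule-associated proteins. The WT libraries held 63560939, 57154757 and 67044409 counts. The Mark3-KO libraries held 71445243, 56925883 and 59098701 counts. Levels are CPM (counts scaled to library size) as mean ± SD of 3 libraries per group, and fold changes are Mark3-KO over WT.

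Mark3 (chromosome 12, 111574523 to 111656221, GRCm38, protein coding) fell from 116 ± 2.78 CPM in WT to 48.0 ± 4.14 CPM in Mark3-KO, which left 41.4% of the WT level. Its counts were 6575, 6475 and 7887 in the WT libraries and 3506, 3120 and 2712 in the Mark3-KO libraries. The log2 fold change was -1.27 (SE 0.10), with an adjusted p of 0.0153 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Counts over the whole gene do not resolve which exons were removed. The log2 fold change stayed between -1.35 and -1.22 with any library left out. The edgeR adjusted p was 0.128 without WT replicate 2, 0.0798 without Mark3-KO replicate 2, and 0.0681 without Mark3-KO replicate 3. With the GC correction the log2 fold change was -1.76 (SE 0.14, edgeR adjusted p 0.0098). Over all alternatives the adjusted p ran from 0.00223 to 0.128 in edgeR fits, and was 0.0138 with limma-voom and 2.44e-20 with the DESeq2 Wald test.

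The other members of the kinase family did not pass the threshold in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Mark4 measured 34.0 ± 13.5 CPM in WT and 15.9 ± 3.16 CPM in Mark3-KO (log2 fold change -1.10, adjusted p 0.0538), and its sign turned to 0.34 after the GC correction. Mark2 measured 40.8 ± 8.49 and 27.5 ± 1.61 CPM (-0.57, adjusted p 0.055), and likewise turned to 0.50. Mark1 had a log2 fold change of -0.20 (adjusted p 0.246). Jag1, a Notch ligand, measured 36.0 ± 3.27 CPM in WT and 32.2 ± 0.61 CPM in Mark3-KO, a log2 fold change of -0.16 (SE 0.11, adjusted p 0.294).

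**Figure D1:**
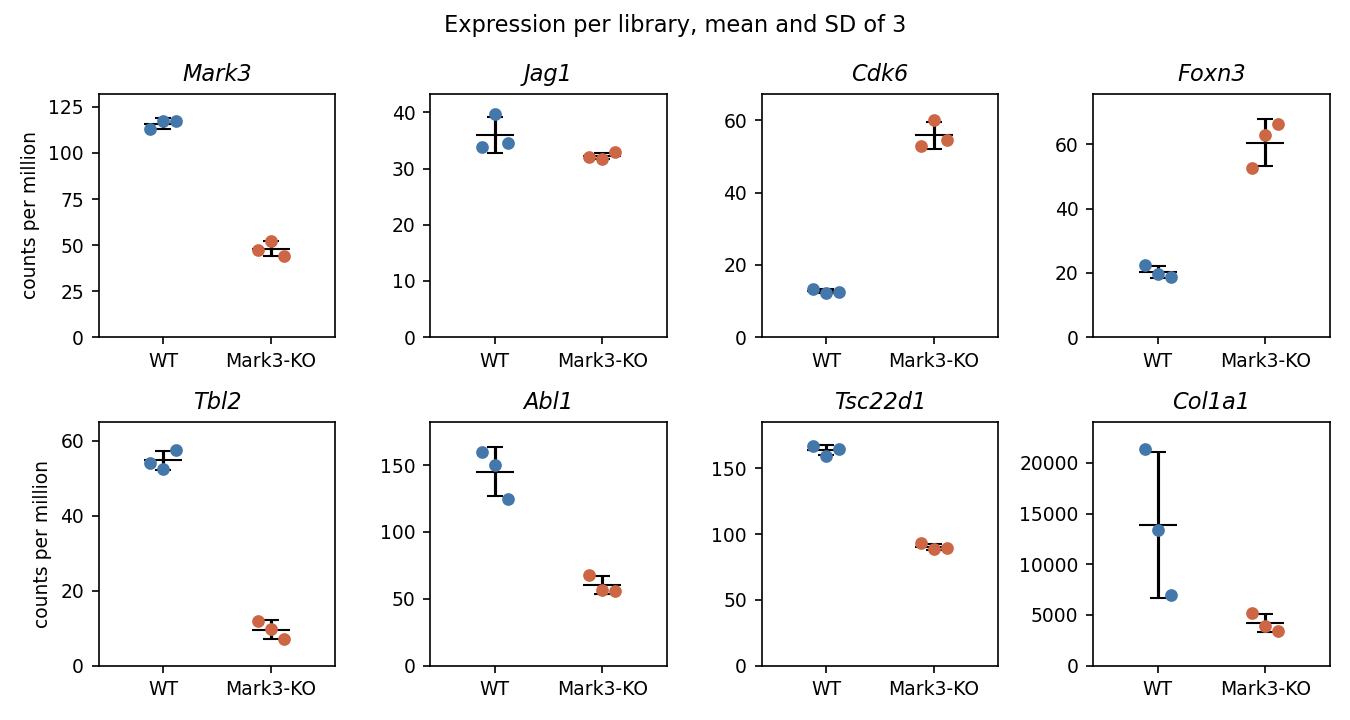
Expression of 8 genes in CPM, 1 point per library, with the mean and SD of 3 libraries in WT and Mark3-KO. Mark3 fell from 116 to 48.0 CPM and Cdk6 rose from 12.7 to 55.8 CPM, while the Col1a1 values of the 3 WT libraries were spread widely; Abl1 and Tsc22d1 were chosen after their values were seen.

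Cdk6, a cyclin-dependent kinase of the G1 phase of the cell cycle (chromosome 5, 3341485 to 3531008), rose from 12.7 ± 0.57 to 55.8 ± 3.73 CPM, a log2 fold change of 2.13 (SE 0.11). Foxn3, a forkhead transcription factor (chromosome 12, 99190078 to 99563582), rose from 20.3 ± 1.87 to 60.6 ± 7.19 CPM (1.57, SE 0.14). Ppp6c, the catalytic subunit of protein phosphatase 6, rose from 43.5 ± 4.24 to 102 ± 16.2 CPM (1.23, SE 0.15). Lifr, a receptor subunit for leukaemia inhibitory factor, rose from 33.6 ± 1.83 to 65.7 ± 6.84 CPM (0.97, SE 0.12). The adjusted p in edgeR's quasi-likelihood test was 0.00276 for Cdk6, 0.0201 for Foxn3, 0.0459 for Ppp6c and 0.0459 for Lifr. After the GC correction the log2 fold changes were 1.84 for Cdk6, 1.31 for Foxn3, 0.62 for Ppp6c and 0.62 for Lifr, and Lifr no longer passed. Ggnbp1 rose from 1.07 ± 0.39 to 15.1 ± 0.42 CPM (3.81, SE 0.28), Rnasek from 1.25 ± 0.38 to 6.93 ± 1.03 CPM (2.48, SE 0.27) and the microRNA gene Mir1906-1 from 0.69 ± 0.24 to 4.11 ± 0.18 CPM (2.57, SE 0.28). Corrected for GC content these were larger, at 4.69 for Ggnbp1, 3.58 for Rnasek and 3.14 for Mir1906-1. Each of these last genes shares exon bases with a gene of opposite direction (Bak1, Gm21988 and Meg3), so its counts depend on how shared reads were assigned. The features Gm21982 and Mir7652, outside the rule and chosen after their values were seen, also rose, the former from 0.116 to 7.31 CPM and the latter by a ratio of 29.3 (95% interval 9.74 to 145, 3 counts in WT). Gm21982 shares exon bases with Rbm42 and Haus5, and Mir7652 with G3bp1, all of opposite direction, so the same limit holds for both.

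Zbtb9, a zinc finger protein gene (chromosome 17, 26973167 to 27008376), was at 15.5 ± 0.72 CPM in WT and had 0 counts in each Mark3-KO library, at least 1010-fold lower. Ggnbp1, the next tested gene on the same strand, gained almost what Zbtb9 lost (their sum was 16.59 CPM in WT and 15.12 CPM in Mark3-KO), and how reads were assigned between neighbours is not known. Moap1, which encodes a Bax-binding regulator of apoptosis, had 1086 counts in WT and 1 in Mark3-KO, a ratio of 1170 (95% interval 210 to 46300), and shares exon bases with Gm20604, which moved the other way. Tnfsf12, which encodes the cytokine TWEAK, fell from 3.99 ± 1.16 to 0.057 ± 0.059 CPM (log2 fold change -6.09, and -4.94 with the GC correction). Tnfsf12 shares exon bases with Tnfsfm13 (log2 fold change -0.08, edgeR adjusted p 0.844), so its counts also depend on how shared reads were assigned. The sum of both genes fell from 5.16 CPM in WT to 1.16 CPM in Mark3-KO. Tbl2 fell from 54.7 ± 2.62 to 9.63 ± 2.46 CPM (log2 fold change -2.51, SE 0.21). Pip5k1c, a lipid kinase that makes phosphatidylinositol bisphosphate, fell from 66.0 ± 22.3 to 6.53 ± 2.73 CPM (-3.33, SE 0.40). Pygo2, a co-activator of Wnt signalling, fell from 45.7 ± 7.16 to 6.46 ± 2.71 CPM (-2.82, SE 0.31), but did not pass after the GC correction (-1.83). Pip5k1c was at -2.11 and Klhl26 at -1.98 after the GC correction, and both passed. Klhl26 (-3.16), Ankrd39 (-3.65), Tmem161a (-2.99) and Lrrc75b (-2.76) completed the 10 named genes that fell. The last 3 were at -3.24, -2.15 and -2.16 with the GC correction. Their adjusted p in edgeR's quasi-likelihood test ran from 0.00276 for Zbtb9 to 0.0459 for Pip5k1c and Tmem161a. Among genes chosen after their values were seen, the stress granule protein gene G3bp1 fell from 240 ± 14.5 to 99.8 ± 18.6 CPM (-1.26), and the mitochondrial fission regulator Mief1 from 39.0 ± 2.15 to 12.7 ± 0.29 CPM (-1.62). Gins2, a DNA replication factor, fell by 2.10 and the tyrosine kinase gene Abl1 by 1.27 on the log2 scale. After the GC correction Abl1 was at -0.37 and no longer passed, and Tsc22d1, which fell by 0.86, turned to 0.21.

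In all, 41 of 19017 tested genes passed in edgeR's quasi-likelihood test with Benjamini-Hochberg adjusted p below 0.05, of which 9 rose and 32 fell, and 5 were predicted models or clones. The CPM of the groups did not overlap for any of the 41, as for 53.3% of all tested genes, where random labels give 10% per gene. Genes moved together along a first principal component that ordered the libraries by group, so this share does not measure an excess over chance. The count lay at an edge, since 4707 genes had an adjusted p below 0.055 and 8317 below 0.1 (3746 higher and 4571 lower). It moved to 14 without WT replicate 1, 0 without WT replicate 2 (5929 genes at an unadjusted p below 0.05), 6460 without WT replicate 3, 6265 without Mark3-KO replicate 1, 3 without Mark3-KO replicate 2 and 5 without Mark3-KO replicate 3. With all libraries, it moved to 8487 with the replicate number as a block, 6915 with the DESeq2 Wald test, 27 with limma-voom, and 5266 with a filter of 1 CPM. Scaling by library size alone gave 2190 higher and 2320 lower genes (51.4% lower, against 78%) and moved the median log2 fold change of all genes from 0.02 to 0.13, so changes are relative to the TMM scale. The GC correction gave 72 genes, 16 higher and 56 lower, of which 33 were among the 41. With the 4 libraries nearest on the main axis (without WT replicate 1 and Mark3-KO replicate 3), 0 genes passed and 3258 had an unadjusted p below 0.05.

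The libraries stood apart along the GC content of transcripts. In the 10% of genes with the highest GC content (57.2 to 78.3%), the median log2 ratio to the mean of all libraries was 1.12, 0.69 and 0.11 in the WT libraries and -0.19, -0.69 and -0.98 in the Mark3-KO libraries. The first principal component held 65.5% of the variance, with scores of -90.2, -58.7 and -10.9 in WT and 15.7, 60.2 and 83.8 in Mark3-KO. With the GC correction it held 44.2%, with the libraries in the same order (-56.2, -39.4 and -7.9 in WT, 10.1, 41.1 and 52.2 in Mark3-KO). The share of mitochondrial transcripts was 1.05, 1.42 and 1.66% in WT and 2.07, 2.38 and 3.22% in Mark3-KO. Ribosomal protein genes took 4.55, 4.09 and 3.69% in WT and 3.67, 3.04 and 2.73% in Mark3-KO. The top 20 genes took 13.6 to 15% of WT counts and 12.2 to 12.8% of Mark3-KO counts. Col1a1, the gene of the main collagen chain of bone, took 1.96, 1.29 and 0.70% of WT counts and 0.531, 0.413 and 0.355% of Mark3-KO counts.

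**Figure D2:**
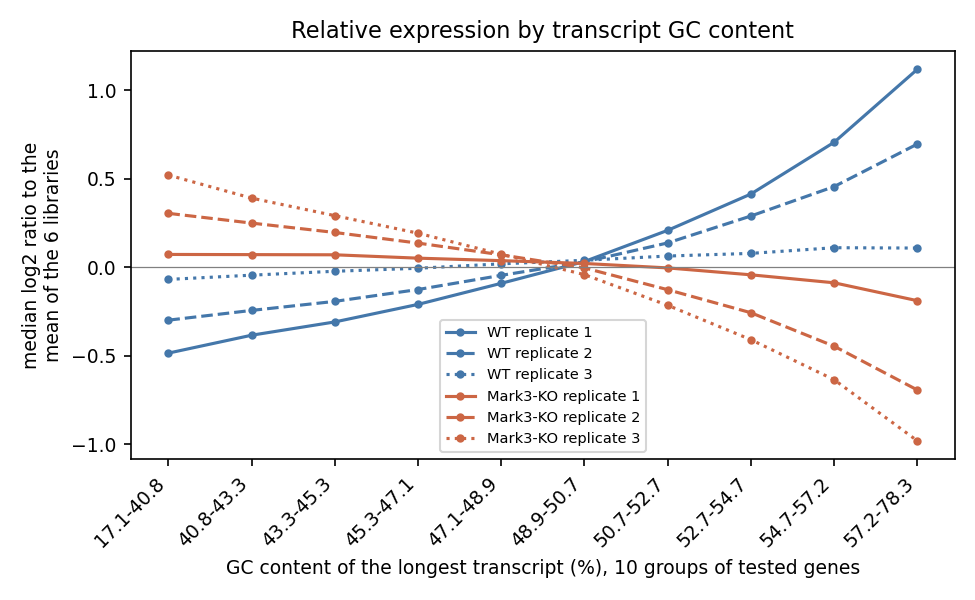
Median log2 ratio of each library to the mean of the 6 libraries, for 10 groups of tested genes of about equal size, ordered by the GC content (%) of the longest transcript, with 1 line per library (WT blue, Mark3-KO orange). At the highest GC content the WT lines lie between 0.11 and 1.12 and the Mark3-KO lines between -0.98 and -0.19, and lines of 1 group differ from each other as well.

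Of 501 distinct list members tested, Mark3 was the one that passed over all genes in edgeR's quasi-likelihood test, while 282 had an unadjusted p below 0.05 and 251 passed with the DESeq2 Wald test. With camera, 9 of 26 lists were lower in Mark3-KO against all other genes and 0 were higher. Each of the 9 had an adjusted p of 0.582 or 0.616 with an estimated correlation, so 0 lists passed that way, and fry passed 4. After the GC correction 3 of the 9 still passed camera, namely cytoskeleton, hypoxia and glycolysis, and skeletal muscle.

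Cytoskeletal genes were lower as a list (median log2 fold change -0.61, camera adjusted p 0.00367; adjusted p = 0.582 with an estimated correlation). Adjusted over the list alone, 1 of 24 was higher and 16 were lower in edgeR's test, among them Tpm2 (317 ± 80.1 to 164 ± 23.0 CPM) and Tubb2b (55.0 ± 18.5 to 20.8 ± 8.32 CPM). The median was -0.09 after the GC correction (camera adjusted p 0.0448; adjusted p = 0.757 with an estimated correlation). Genes of hypoxia and glycolysis had a median of -0.64 (camera adjusted p 0.00562; adjusted p = 0.582 with an estimated correlation), with 1 higher and 14 lower of 22 adjusted over the list alone. The glycolytic enzyme gene Pfkl measured 125 ± 48.5 and 37.0 ± 16.1 CPM, Gpi1 329 ± 51.2 and 172 ± 43.2 CPM. Their median was -0.36 after the GC correction (camera adjusted p 0.00242; adjusted p = 0.757 with an estimated correlation). Skeletal muscle markers, at low levels, had a median of -1.12 (camera adjusted p 0.00798; adjusted p = 0.582 with an estimated correlation), with 0 higher and 4 lower of 9 adjusted over the list alone. Acta1, the skeletal actin gene, measured 5.02 ± 2.16 and 0.924 ± 0.419 CPM, and the list's median was -0.82 after the GC correction (camera adjusted p 0.00436; adjusted p = 0.833 with an estimated correlation). After this correction 0 cytoskeletal genes were higher and 6 lower, 0 and 6 of hypoxia and glycolysis, and 0 and 2 of skeletal muscle, adjusted over the list alone. The log2 fold change moved from -0.95 to -0.18 for Tpm2, from -1.75 to -0.75 for Pfkl and from -2.43 to -1.42 for Acta1.

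The list of Notch ligands, receptors and processing genes was lower (median -0.43, camera adjusted p 0.00798; adjusted p = 0.582 with an estimated correlation), with 2 higher and 11 lower of 23 adjusted over the list alone in edgeR's test. Notch1 measured 44.4 ± 16.4 CPM in WT and 16.8 ± 4.94 CPM in Mark3-KO, and Notch3 34.3 ± 13.8 and 13.5 ± 3.92 CPM. With the GC correction the log2 fold change moved from -1.40 to -0.36 for Notch1 and from -1.35 to -0.02 for Notch3. The list's median was then -0.07 (camera adjusted p 0.0731; fry adjusted p 0.0212, against 0.0526 without the correction), and 0 members passed adjusted over the list alone. Notch target genes did not pass (median -0.04, camera adjusted p 0.696). Of 8 targets, 1 was lower adjusted over the list alone, Hey1, at 0.427 ± 0.093 and 0.102 ± 0.046 CPM, and Hes1 measured 8.06 ± 0.59 and 6.56 ± 0.31 CPM. The log2 fold change of Hes1 moved from -0.30 to -0.14 after the GC correction, where 1 target was lower adjusted over the list alone.

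Extracellular matrix genes were lower as a list (median -0.33, camera adjusted p 0.0184; adjusted p = 0.582 with an estimated correlation), with 3 higher and 18 lower of 36 adjusted over the list alone in edgeR's test. Fibronectin (Fn1) measured 22009 ± 1517 and 14575 ± 1067 CPM, and the collagen cross-linking enzyme gene Lox, on the higher side, 1106 ± 81.3 and 1868 ± 248 CPM. The median was 0.00 after the GC correction and the list no longer passed (camera adjusted p 0.684), with 4 higher and 6 lower adjusted over the list alone. Fn1 moved from -0.59 to -0.10 and Lox from 0.76 to 0.38. Genes of osteoblast differentiation and mineralisation did not pass (median -0.30, camera adjusted p 0.0633), with 3 higher and 9 lower of 25 adjusted over the list alone. They passed without WT replicate 1 (camera adjusted p 0.0467; adjusted p = 0.658 with an estimated correlation) or WT replicate 3 (0.0183; adjusted p = 0.639 with an estimated correlation), and their median was -0.05 after the GC correction, where 0 members passed adjusted over the list alone. Col1a1 measured 13907 ± 7188 and 4167 ± 889 CPM (log2 fold change -1.74, adjusted p 0.0506), with -0.43 after the GC correction. Runx2, a transcription factor of osteoblast differentiation chosen after its values were seen, measured 71.2 ± 9.86 and 57.7 ± 6.22 CPM (-0.30, adjusted p 0.133). The osteocalcin gene Bglap2 measured 1.30 ± 0.31 and 0.418 ± 0.187 CPM. Runx2 was at -0.17 after the GC correction, and Bglap2 moved from -1.62 to -0.78.

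The list named for LKB1-dependent AMPK-related kinases holds the deleted gene Mark3, and also Stk11, which encodes LKB1 itself. It was lower (median -0.48, camera adjusted p 0.0184, and 0.582 with an estimated correlation), with 1 higher and 9 lower of 15 adjusted over the list alone. Stk11 measured 50.2 ± 16.8 and 16.7 ± 5.05 CPM. The genes neighbouring Mark3 were also lower (median -0.53, camera adjusted p 0.0184, and 0.582 with an estimated correlation), with 0 higher and 7 lower of 10 adjusted over the list alone. Among them were Klc1 (106 ± 26.7 and 50.1 ± 12.2 CPM) and Ckb (30.2 ± 19.6 and 7.45 ± 3.72 CPM). Ckb was uneven across the WT libraries, at 51.2, 27.0 and 12.3 CPM. Immediate early genes had a median of -0.55 (camera adjusted p 0.00562; adjusted p = 0.616 with an estimated correlation), and 0 of 19 passed adjusted over the list alone, with 9 at an unadjusted p below 0.05 in edgeR's test and 8 past the threshold with the DESeq2 Wald test. Junb measured 34.2, 9.51 and 2.38 CPM in the WT libraries and 0.969 ± 0.698 CPM in Mark3-KO, so its WT level rested on WT replicate 1, and the Junb log2 fold change was -2.61 without that library. Chondrocyte markers had a median of -0.57 (camera adjusted p 0.0361; adjusted p = 0.582 with an estimated correlation), with 0 higher and 4 lower of 11 adjusted over the list alone, and did not pass without Mark3-KO replicate 1 (camera adjusted p 0.0903) or with a filter of 1 CPM (0.111). None of these lists passed camera after the GC correction, where the medians were -0.07 for the kinases, 0.00 for the neighbours, -0.06 for the immediate early genes and -0.27 for the chondrocyte markers. Adjusted over the list alone, the corrected counts were 3 higher and 2 lower for the kinases, 1 and 2 for the neighbours, 3 and 2 for the immediate early genes and 1 and 2 for the chondrocyte markers. Stk11 moved from -1.59 to -0.31, Klc1 from -1.08 to -0.22, Ckb from -2.02 to -0.46 and Junb from -3.97 to -2.21.

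Other lists did not pass camera. Cell cycle genes had 17 higher and 8 lower of 39 adjusted over the list alone in edgeR's test (median 0.13, mean -0.02, camera adjusted p 0.235). Cenpf, a kinetochore protein gene, measured 118 ± 16.8 and 189 ± 21.9 CPM, and Cdt1, a replication licensing factor, 11.98 ± 5.87 and 1.47 ± 0.54 CPM. Target genes of p53 had 9 higher and 9 lower of 30 (median -0.07, camera adjusted p 0.879), with Apaf1 at 107 ± 8.36 and 159 ± 11.7 CPM and Aen at 134 ± 12.6 and 29.7 ± 14.6 CPM. The BMP and TGF-beta list had 8 higher and 10 lower of 29 (median -0.23, camera adjusted p 0.514), with Tgfbr1 at 26.1 ± 4.78 and 44.7 ± 8.05 CPM and Id3 at 58.2 ± 35.4 and 10.6 ± 5.55 CPM. The Wnt list had 1 higher and 7 lower of 31 (median -0.25, camera adjusted p 0.0547), with Axin2 at 6.82 ± 1.65 and 3.21 ± 0.47 CPM, and passed without WT replicate 1, WT replicate 3 or Mark3-KO replicate 2 (camera adjusted p 0.0467, 0.0163 and 0.0402; adjusted p = 0.666, 0.639 and 0.679 with an estimated correlation). Osteoclast regulators had 2 higher and 3 lower of 12 (median 0.07, mean -0.11, camera adjusted p 0.987), and YAP and TEAD targets 0 higher and 3 lower of 20 (median -0.29, camera adjusted p 0.12). All of these counts were adjusted over the list alone. Corrected for GC content they were 0 higher and 1 lower for the cell cycle, 2 and 3 for p53 targets, 5 and 6 for BMP and TGF-beta, 0 and 0 for Wnt, 0 and 1 for osteoclast regulators, and 0 and 0 for YAP and TEAD targets. Cenpf moved from 0.68 to 0.28, Cdt1 from -3.02 to -1.89, Apaf1 from 0.57 to 0.33, Tgfbr1 from 0.78 to 0.28, Id3 from -2.46 to -1.61 and Axin2 from -1.09 to -0.40 on the log2 scale.

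**Figure D3:**
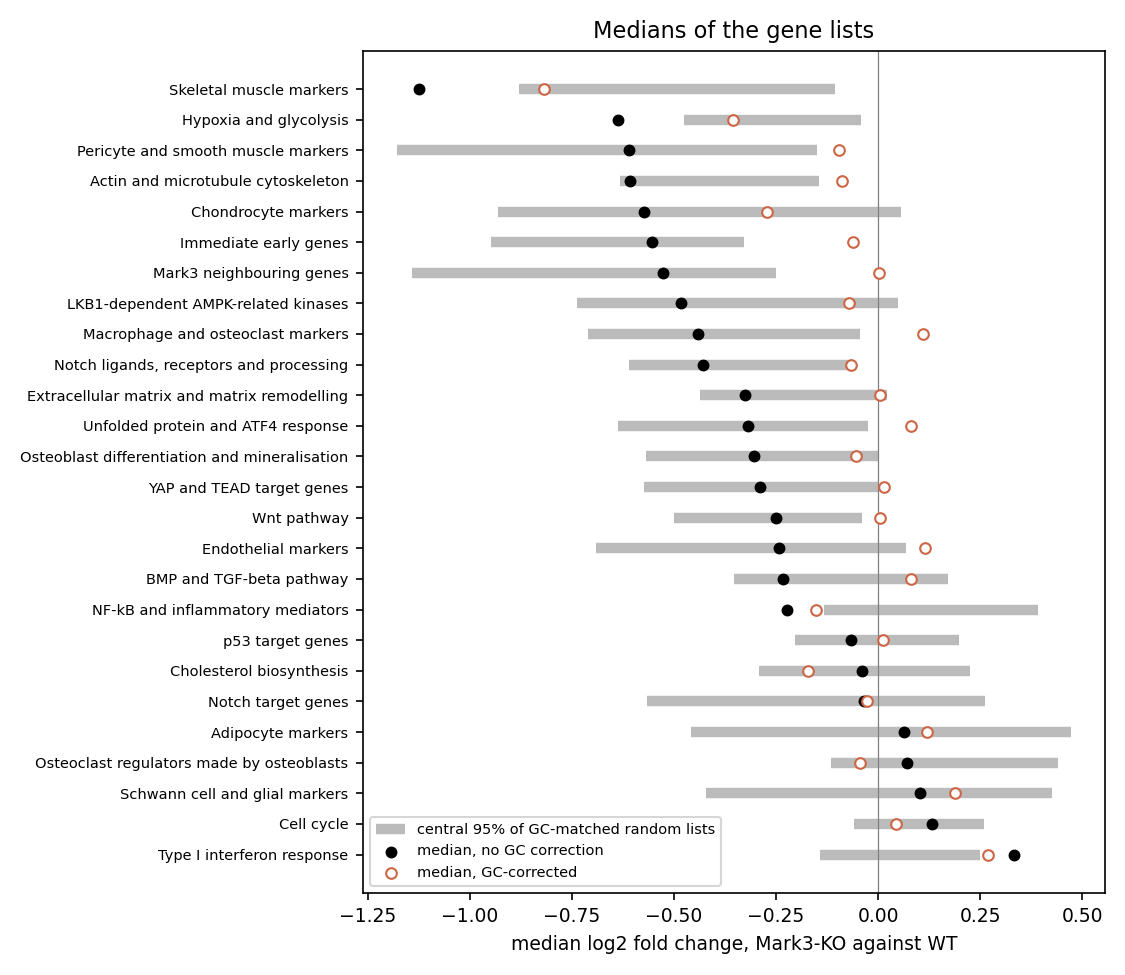
Median log2 fold change of each gene list without (filled) and with (open) the GC correction, with grey bars for the central 95% of 1000 random lists matched on GC content to the uncorrected list. The uncorrected medians of hypoxia and glycolysis (-0.64), skeletal muscle markers (-1.12) and NF-kB mediators (-0.22) lie below their bars and that of the type I interferon response (0.33) above its bar, and most corrected medians lie nearer to 0.

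Stress and inflammatory lists were as follows in edgeR's test, with all counts adjusted over the list alone. The type I interferon response had 3 higher and 0 lower of 30 (median 0.33, camera adjusted p 0.0547), with Ifit1 at 83.7 ± 6.72 and 139 ± 28.3 CPM. It passed without WT replicate 1, Mark3-KO replicate 1 or Mark3-KO replicate 3 (camera adjusted p 0.025, 0.0303 and 0.00793; adjusted p = 0.699, 0.811 and 0.626 with an estimated correlation), with the 4 libraries nearest on the main axis (0.00317; adjusted p = 0.63 with an estimated correlation), and after the GC correction (0.0314; adjusted p = 0.833 with an estimated correlation). NF-kB and inflammatory mediators had 5 higher and 8 lower of 19 (median -0.22, camera adjusted p 0.582), with Saa3 at 3.86 ± 0.22 and 1.65 ± 0.44 CPM, and were lower past camera after the GC correction (0.0295; adjusted p = 0.72 with an estimated correlation). Cholesterol biosynthesis had 2 higher and 9 lower of 20 (median -0.04, camera adjusted p 0.259), with Lss at 80.1 ± 5.93 and 58.5 ± 2.49 CPM. It was lower with fry (adjusted p 0.0282) and past camera after the GC correction (0.00436; adjusted p = 0.595 with an estimated correlation). The unfolded protein and ATF4 response had 3 higher and 9 lower of 22 (median -0.32, camera adjusted p 0.189, fry adjusted p 0.0408), with Ddit3 at 54.8 ± 9.86 and 28.0 ± 4.90 CPM. Fry also passed the AMPK-related kinases and the extracellular matrix (adjusted p 0.0408 each). With the GC correction fry passed 2 lists, cholesterol biosynthesis (adjusted p 0.0155) and the Notch ligands, receptors and processing genes. Corrected for GC content the counts were 0 higher and 0 lower for interferon, 0 and 2 for NF-kB, 1 and 7 for cholesterol, and 3 and 4 for the unfolded protein response, and Ifit1 moved from 0.74 to 0.33 on the log2 scale.

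Markers of other cell types did not move as 1 block, with all counts adjusted over the list alone. Pericyte and smooth muscle markers had 1 higher and 4 lower of 9 (median -0.61, camera adjusted p 0.0547), and passed without Mark3-KO replicate 3 (0.0392; adjusted p = 0.626 with an estimated correlation). Macrophage and osteoclast markers had 3 higher and 3 lower of 16 (median -0.44, camera adjusted p 0.539), with Mrc1 at 10.4 ± 1.68 and 16.7 ± 0.92 CPM. Endothelial markers had 1 higher and 1 lower of 8 (median -0.24, camera adjusted p 0.782). Adipocyte markers (0 of 4, none at an unadjusted p below 0.05, median 0.06, camera adjusted p 0.696) and Schwann cell markers (0 of 6, 2 at an unadjusted p below 0.05 in edgeR and 2 past the threshold with DESeq2, median 0.10, camera adjusted p 0.696) did not pass. The epithelial marker Cdh1 (-0.34, adjusted p 0.562) and the red blood cell marker Alas2 (0.44, adjusted p 0.192) were the tested members of their lists and did not pass in edgeR's test. Of 5 sex-linked genes, 4 were higher adjusted over the list alone (median 0.55, and -0.05 after the GC correction). Ddx3y, on the Y chromosome, measured 46.7 ± 10.7 and 68.5 ± 11.8 CPM, and its sign turned after the GC correction (-0.11). After this correction 0 sex-linked genes passed, and the counts of higher and lower genes were 1 and 0 for pericyte, endothelial, adipocyte and red blood cell markers and 0 and 0 for macrophage, Schwann cell and epithelial markers. Mrc1 moved from 0.69 to 0.31 on the log2 scale.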

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

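Of 129 named genes besides Mark3, over all alternatives run, 1266 values kept direction and side of the threshold, 553 newly passed, 81 no longer passed and 27 changed sign. The number of higher and lower genes was 2190 and 2320 with library size alone, 2781 and 4134 with the DESeq2 Wald test (1122 genes without an adjusted p), 2264 and 3002 with the filter of 1 CPM, 16 and 56 with the GC correction, and 3746 and 4571 at an adjusted p below 0.1. It was 0 and 0 with the 4 libraries nearest on the main axis, by edgeR, with 3258 genes at an unadjusted p below 0.05. The lower genes numbered 20 with limma-voom and 52 without a filter. Leaving out each library in turn gave 0 to 2528 higher and 0 to 3932 lower genes. WT replicate 2, Mark3-KO replicate 2 and Mark3-KO replicate 3 each took the total to 5 or fewer when left out. At 0.055, 4707 genes passed in the edgeR test, so small shifts in p move these counts. With the GC correction, 19 higher and 61 lower genes passed at 0.055, and 593 and 1045 at 0.1. The edge between 0.05 and 0.055 was thus absent with the correction, which also removes any true change that follows GC content. Beyond that, the cause of the edge was not tested. Adding the replicate block to the edgeR fit gave 3783 higher and 4704 lower genes. The labels do not say that equal numbers share a litter or culture, so the main fit had no block. Libraries with the same number correlated at 0.329, -0.032 and 0.292 in their deviations from the group means. WT replicate 2 and Mark3-KO replicate 2 did not correlate best with each other. Both lay near their group's mean on the first principal component (-58.7 against -53.3 in WT, 60.2 against 53.3 in Mark3-KO). Libraries of both groups ran in number order on this component, so these correlations neither show nor exclude a pairing.

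Mark3 kept its direction under every alternative run. Its log2 fold change was -1.24 with the 4 libraries, where it no longer passed with 4 samples, -1.35 to -1.22 with each library left out, and -1.76 with the GC correction. The lists past camera were 9, against 0 with an estimated correlation, which widens the null spread, and 4 with fry, which asks a different question.

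After the GC correction these signs turned, as the correction adds to GC-rich and takes from GC-poor genes in Mark3-KO: Mark2 0.50, Mark4 0.34, Sik3 0.033, Tnfaip2 0.41, Notch2 0.055, Olfm2 0.044, Snw1 -0.12, Col1a2 0.13, Ephb4 0.028, Tnfrsf11b -0.13, Sema3a -0.081, Lrp4 0.15, Ajuba 0.57, Col6a1 0.013, Cdh5 0.020, Laptm5 0.17, Col2a1 0.054, Lpl -0.0069, Cebpa 1.35, Eif2s3y -0.055 and Ddx3y -0.11. None of these genes passed in either fit. The Fabp4 log2 fold change, -0.0014, took 0.11 with library size alone, 0.000415 with the DESeq2 Wald test, 0.018 with limma-voom, 0.0085 with the replicate block, and 0.035 to 0.13 without Mark3-KO replicate 2 or WT replicate 2. Depth limits genes near 0 counts, where the fold is set by a few counts.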

Other observations

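After the GC correction, 72 genes passed in edgeR's quasi-likelihood test, and those named here were chosen after their values were seen. Genes that passed with this correction and not without it, lower in both fits, included Bcl2l11, which encodes the pro-apoptotic protein Bim (22.045 ± 2.03 to 11.9 ± 0.37 CPM, corrected log2 fold change -0.95, edgeR adjusted p 0.0157), and Stat5b, a transcription factor of cytokine signalling (39.8 ± 9.35 to 16.3 ± 2.25 CPM, -0.89, 0.0475). Camkk2, a kinase upstream of AMPK (43.7 ± 6.80 to 19.8 ± 3.92 CPM, -0.69, 0.0344), and Pfkfb3, a regulator of glycolysis (31.6 ± 1.88 to 14.0 ± 3.04 CPM, -1.06, 0.0444), were among them. The replication licensing gene Cdt1 was at -1.89 (0.0157). Cenpb, a centromere protein gene, was higher in both fits and passed with the correction (17.9 ± 4.18 to 46.8 ± 12.6 CPM, 2.32, 0.0144). Each gene named so far had an edgeR adjusted p of 0.0506 without the correction, just above the threshold. Other calls arose with the correction itself. Irx3 went from 0.143 (edgeR adjusted p 0.759) to 1.757, Dnaaf2 from 0.172 (0.475) to 1.02 and Syne3 from 0.323 (0.376) to 1.085.

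The tests of the group on the main axis and of called genes under the GC correction were chosen after the result was seen, as was the GC correction itself. The main axis of variation separated WT from Mark3-KO but also spread the libraries of each group. Across genes, which are not independent replicates, the weight on this axis had a Spearman rho of -0.801 with GC content, while the rho with transcript length was 0.062, which argues against length. The difference between replicates 1 and 3 within WT and that within Mark3-KO, which share no library, had a rho of 0.545. This argues against a fixed effect of the deletion, or of Cre in place of GFP, as the whole source of the axis, since differences within a group hold neither. An effect of the virus or the deletion that varied between libraries of a group is not excluded. A GC trend from library preparation or RNA quality may have contributed, or a state of the cultures that varied between wells and with the virus; the counts hold no batch or quality record to test these. With the GC correction the first component still held 44.2% of the variance with the libraries in the same order, so the deletion, the Cre virus, the GC trend and a culture state remain partly confounded.

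Of the 41 called genes, 80.5% passed in the same direction after the GC correction. The GC trend also spread the libraries within each group, so the uncorrected test favoured genes that follow the trend less. A high share was therefore likely in advance, and it does not weigh the trend as a cause of changes among all genes. At 0.055, 4707 genes passed without the correction, but 19 higher and 61 lower genes with it. For the kept calls, a fold beyond the fitted trend remained. Of these 33 kept calls, 23 shrank and 10 grew (median ratio of sizes 0.888) and 28 had a smaller SE, and some halved, such as Rnf26 from -2.09 to -1.05 and Ppp6c from 1.23 to 0.62, so the trend may account for part of their size, and the deletion, the Cre virus or a culture state that varied with the group could each hold the rest. In the calls that ended, the fold shrank from -1.27 (SE 0.14) to -0.37 (SE 0.11) for Abl1, from -1.51 (SE 0.19) to -0.27 (SE 0.22) for Kctd15, from -1.30 (SE 0.14) to -0.66 (SE 0.13) for Pigq, from -2.82 (SE 0.31) to -1.83 (SE 0.34) for Pygo2 and from 0.97 (SE 0.12) to 0.62 (SE 0.10) for Lifr. It also went from -2.82 (SE 0.33) to -2.21 (SE 0.35) for Gm15501 and from -2.59 (SE 0.30) to -1.67 (SE 0.30) for Gm6473, and the sign turned for Tsc22d1. The Gm15501 fold stayed large, so the end of that call does not show the GC trend as its source. Of the 9 lists past camera, 33.3% passed after the GC correction, a share between the bounds set for and against GC content as their cause. This share does not tell the GC trend and a change of the lists apart. Uncorrected medians of hypoxia and glycolysis (-0.64) and skeletal muscle (-1.12) lay below the central range of random lists matched on GC content (lower ends -0.48 and -0.88). A GC trend alone would seldom give these medians, unless members of a list move together. The rest of the 9 lay within their ranges, the cytoskeleton included (-0.61, range -0.63 to -0.14). Their medians were thus no lower than GC content alone could give. In 1 of 10 splits of the 6 libraries into 3 and 3, the real one, as many as 41 genes passed, and the highest of the others gave 1 gene (72 and 3 after the GC correction), but 10 splits are too few for a share under 0.05.

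Several of the largest folds lay in genes that overlap others. Of the 9 called genes beyond 3 on the log2 scale, 44.4% (95% exact interval 13.7 to 78.8%) shared exon bases with a tested gene that moved the other way by over 0.5, between the bounds set for and against reads assigned differently, so this cannot be told apart from separate changes of each gene. Among all called genes the share was 22% (10.6 to 37.6%), against 3.1% of all tested genes (two-sided Fisher's exact p 3.56e-06, called genes against the rest). The interval and p treat genes as independent, though G3bp1 and Mir7652 count as each other's partner. Partners entered by fold alone, as did Mfrp for Rnf26 (log2 fold change 0.55, edgeR adjusted p 0.488). The summed level of a called gene and its partner stayed near its value in some pairs, as a shift of reads between partners could give: Moap1 with Gm20604 (17.4 CPM in WT, 19.5 in Mark3-KO), Rnasek with Gm21988 (11.4 and 10.1), Gm21982 with Haus5 (10.4 and 10.7) and Gm28557 with Zfp708 (5.90 and 6.34). It fell short in others, namely Gm21982 with Rbm42 (31.0 and 8.86), Ggnbp1 with its exon partner Bak1 (59.3 and 40.2), Mir1906-1 with Meg3 (345 and 104), G3bp1 with Mir7652 (239.5 and 100.3), Gm28557 with Rslcan18 (5.57 and 3.67) and Rnf26 with Mfrp (80.2 and 20.99). Zbtb9 shares no exon bases with a tested gene. The sum with its neighbour Ggnbp1 on the same strand stayed near its value (16.59 and 15.12 CPM), so a shift of reads could reach these genes as well. A neighbour on the same strand within 50 kb moved the other way for 19.5% of called and 9.01% of all tested genes (two-sided Fisher's exact p 0.0278, called genes against the rest). This test was chosen after the result was seen. Zbtb9 and Ggnbp1 are both among the 8 such called genes and count each other, so the p is no support independent of this pair.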
